A study of Homo sapiens with 2 samples.

How the data were processed

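Chromatin from HCT-116 cells was crosslinked with formaldehyde, sonicated, digested with micrococcal nuclease, pre-cleared with rabbit IgG and immunoprecipitated with a polyclonal anti-APC antibody, per the labels' protocols. The series holds 1 anti-APC library and 1 library of pre-cleared input, and the groups APC ChIP and input were taken from the sample titles. A single table of annotated peaks was analysed. MACS2 was used and coordinates are on hg19, per the submitters' processing notes. The MACS2 version, the aligner, the calling threshold, the use of the input as control, the annotation tool and the treatment of reads that map to several places are not given in the sources used here.

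The deposited score column is not a strength: in all 44771 rows the score equals the end minus the start plus 2 bp, so it is a peak length, and it is used here only as a length. Lengths ran from 352 to 41681 bp with a median of 1350 bp. Per the file headers, each row also gives an annotation of the peak, a more detailed annotation that includes repeats, the signed distance in bp to a TSS, and the name and type of that gene. The distance runs from the peak centre, so a long peak can cover a TSS that its centre lies some kb away from. Rows labelled promoter had distances of -999 to 983 bp. No peaks overlapped one another. Peaks name 1 gene each, so a peak shared by neighbouring genes counts for one of them. The number of reads behind a peak is unknown, so no floor or interval based on reads was computed. A longer call can come from deeper sequencing or from the caller's settings for joining regions, and lengths are compared only within this list.

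Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9. Shares of peaks have 95% Wilson intervals, and peaks per chromosome have exact 95% Poisson intervals. Median lengths of promoter, intergenic, intronic and exonic peaks were compared with two-sided permutation tests of 100000 resamples, Benjamini-Hochberg adjusted over 3 comparisons. Gene lists were fixed before the data were examined, as were the comparisons, the rule for named genes and the alternatives, except those named as added. A gene was linked if it was the named gene of a peak whose centre lay within 10 kb of its TSS. The number of linked members of each list was set against 10000 random lists of the same size, which redraws list membership over genes as a permutation test, with a two-sided p of 0.0002 at the smallest, adjusted over 19 lists. The background was 20037 protein-coding genes of the RefSeq table of GRCh38.p14, used for names, gene types and gene order only. Of 13691 protein-coding names in the peak list, 13485 (98.5%) matched it by current or older symbol. Matching of random lists on gene length had been planned, but lengths on the build of the peaks were not used here, so the lists are unmatched. Of 659 background genes with a LOC symbol 1 was linked, so a background without them was added as an alternative.

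Both tests were checked on simulated data. With 20037 genes at the observed linking rate, 78.6% of simulated lists of 30 genes raised to 80% linked were called, and 0.571% of lists left at that rate. Links were simulated independently for each gene and lists were drawn at random. The check therefore does not cover lists of neighbouring genes, such as the HOX clusters, whose links can depend on one another. With 1000 lengths per group, 100 of 100 pairs with lengths raised 1.3-fold were called, and 4 of 100 pairs with no difference.

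Genes were named by a fixed rule: those of the 15 longest peaks, those of the 10 longest promoter peaks, up to 4 linked members of each list with the longest linked peaks, 25 WNT, AP-1 and colon genes whatever their values, and the 10 genes with most peaks. A few genes that the rule takes are not reported here. The rule spoke of the strongest peaks, for which the length had to stand in. Alternatives were peaks of at least the median length (1350 bp), peaks of at least the third-quartile length (2135 bp), merging of peaks within 500 bp, leaving out satellite, simple, low-complexity and rRNA repeats, links within 1 kb, 50 kb or any distance, Fisher's exact test, means of log2 lengths, a background of genes named for any peak, and the number of linked peaks per gene. Leaving out SINE-centred peaks and LOC symbols was added after the data were seen. Motifs and random placement of peaks were not analysed here, as they need the genome sequence and annotation of the build.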

Results

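The series profiled the chromatin binding of APC, the tumour suppressor protein that holds β-catenin in check in the WNT pathway, in HCT-116 cells. HCT-116 is an established human colon carcinoma line whose APC gene is intact and whose β-catenin resists degradation. It comprised 1 chromatin immunoprecipitation library made with an antibody against the C-terminal end of APC and 1 input library. The data analysed were a single list of 44771 peaks in hg19 coordinates, each with the gene of its nearest annotated transcription start site (TSS). There were no replicates, so no difference between libraries was tested, and every test below compares peaks or genes within this list. The list gave no read counts, so the sequencing depth is unknown and the intervals given cover counting error only.

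The first question was where in the genome the APC peaks lie. The peaks covered 78.5 Mb on 24 chromosomes. Most were intronic (20403 peaks, 45.6%, 95% Wilson interval 45.1 to 46.0) or intergenic (16173 peaks, 36.1%, interval 35.7 to 36.6). Promoters held 5022 peaks (11.2%, interval 10.9 to 11.5). Exons held 2.14%, transcription termination sites 2.03%, 5′ UTRs 1.38%, non-coding transcripts 0.786% and 3′ UTRs 0.753% of the peaks. The promoter share was 19.1% among peaks of at least the median length of 1350 bp. It was 18.3% without peaks labelled as centred in SINE repeats, a class of short interspersed elements that labelled 38.7% of all peaks. The detailed annotation kept 5020 of the 5022 promoter peaks and all 956 exon peaks under their own class. Repeat labels thus fell almost only on intronic and intergenic peaks, and leaving out SINE-centred peaks raised the promoter share by construction.

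Peaks were concentrated around start sites. By their centres, 8098 peaks (18.1%, interval 17.7 to 18.4) lay within 1 kb of the TSS of the named gene, 16846 (37.6%) within 10 kb, and 5901 (13.2%, interval 12.9 to 13.5) beyond 100 kb. The share downstream of the TSS was alike within 1 kb (59.2%, interval 58.1 to 60.3) and over all peaks (58.9%, interval 58.4 to 59.3). The median absolute distance over all peaks was 18291 bp.

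**Figure D1:**
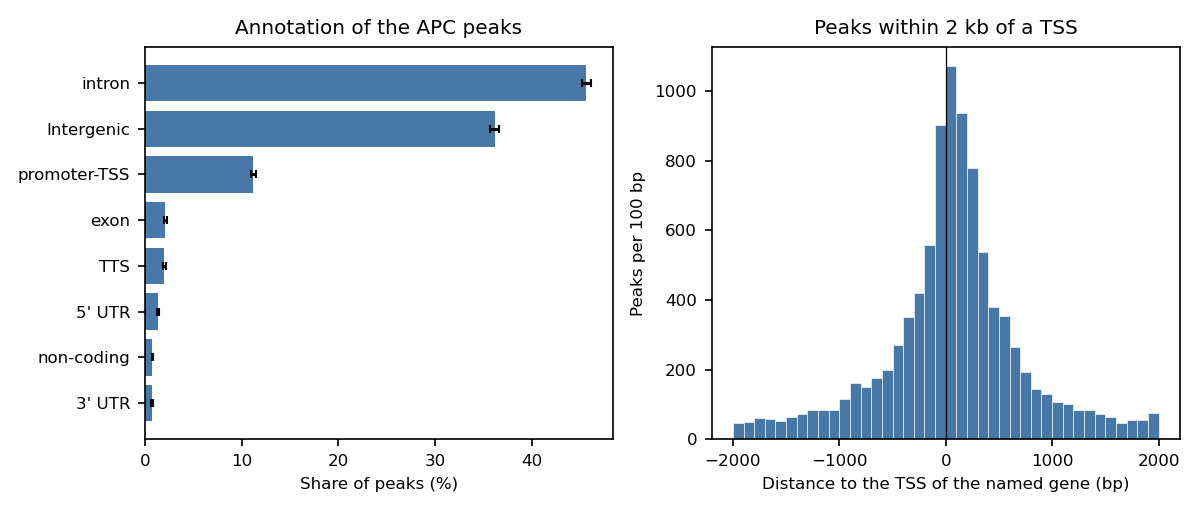
Left, share of the 44771 APC peaks in each annotation class in percent, with 95% Wilson intervals as error bars. Right, number of peaks per 100 bp against the signed distance in bp of the peak centre to the TSS of the named gene, negative upstream. Introns hold 45.6% of the peaks, and the counts are highest next to the TSS.

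Promoter peaks were longer than peaks elsewhere. Their median length was 2104 bp, against 1237 bp for intergenic, 1210 bp for intronic and 1843.5 bp for exonic peaks. The promoter median exceeded the intergenic one by 867 bp, the intronic one by 894 bp and the exonic one by 260.5 bp. Each of these 3 differences had an adjusted p of 1e-05, the smallest that 100000 resamples can give (two-sided permutation test of medians, Benjamini-Hochberg adjusted). The score column of the list equals the peak length, so binding strength was not compared. Among peaks of 2135 bp or more the promoter minus intergenic difference was -165 bp, and among peaks of 1350 bp or more the difference from exonic peaks was 64.5 bp (permutation p = 0.161), but both settings select on the measured length itself.

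**Figure D2:**
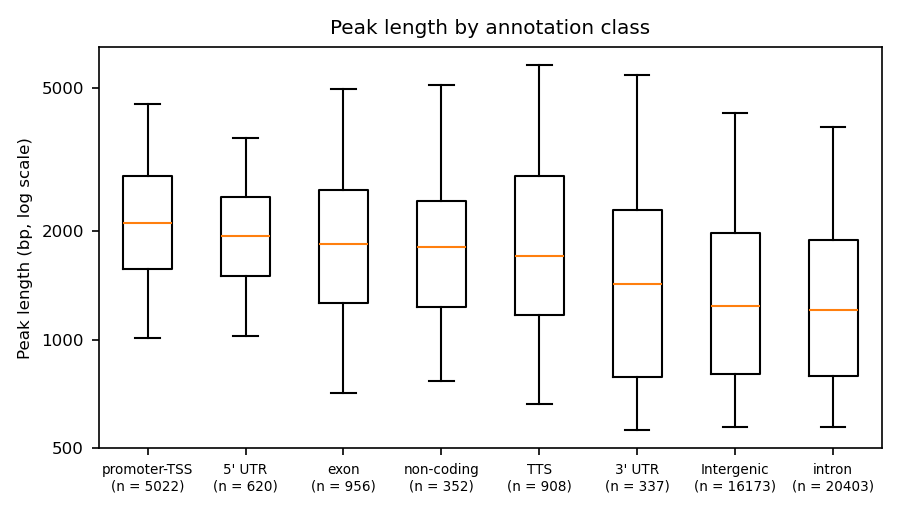
Peak length in bp on a log axis for each annotation class, with the number of peaks under each class name. Lines mark medians, boxes the quartiles and whiskers the 5th and 95th percentiles of this one list; promoter peaks have the highest median, 2104 bp, and intronic peaks the lowest, 1210 bp.

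The longest peak, 41681 bp (chromosome 19, 36758940 to 36800619), was intergenic, was centred in the SST1 satellite and was named for LOC100134317. The next, 41576 bp (chromosome 1, 228743212 to 228784786), was centred in a CpG island 16395 bp upstream of the RHOU TSS and was long enough to cover that TSS. Peaks named for LOC284412 (35639 bp), FCGR2A (35038 bp), LINC00963 (34989 bp), PLS3 (32053 bp) and USP17L30 (25418 bp), a member of a multicopy deubiquitinase family, followed. The FCGR2A and PLS3 peaks were centred 49141 and 147485 bp from the TSS, so these names do not place them at those genes. Peaks over 20 kb were also named for ID1 (25167 bp), an inhibitor of helix-loop-helix factors, BCL9L (24794 bp), a β-catenin coactivator, SLC16A5 (23204 bp), LMNA (22493 bp), which encodes nuclear lamins, HM13-AS1 (21855 bp), IRF2BPL (21578 bp), TOB1 (21387 bp) and ITGB4 (21127 bp), an epithelial integrin. The LOC100134317, IRF2BPL, TOB1 and ITGB4 peaks were centred 22466, 73261, 79512 and 19548 bp from the TSS and were too short to reach it. Their names do not place them at the starts of those genes either. The BCL9L peak (chromosome 11, 118777322 to 118802114) was annotated as intergenic by its centre, 8105 bp upstream of the TSS, but was long enough to cover that TSS. Among promoter peaks, the longest were at TUBB3 (19971 bp), SNAR-A14 (14336 bp), MAFG-AS1 (13123 bp), PLEC (12181 bp), NTSR1 (12037 bp), TSEN54 (11913 bp), CLDN4 (11224 bp), PIEZO1 (10985 bp), SPHK1 (10678 bp) and LOC79999 (10527 bp). SNAR-A14 and USP17L30 belong to near-identical gene copies, among which reads can be split or shared. Whether the other long peaks lie in copied or tandem sequence was not examined beyond the repeat at the peak centre.

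Some genes were named for many peaks, most of them far from the TSS. PCDH7, a protocadherin, had 87 peaks across 3.53 Mb of chromosome 4 (29896512 to 33422363), of which 51 were centred in SINE repeats and 2 lay within 10 kb of the TSS. KRR1 had 32 and PHLDA1 had 28, and together they filled a stretch of chromosome 12 from 75904783 to 76426746. FAT1, an atypical cadherin, had 29 peaks, TRIB1, a pseudokinase gene, had 28 with a median length of 2634 bp, and HS3ST1 had 26. Within 10 kb of the TSS lay 1 of the KRR1, 3 of the PHLDA1, 4 of the FAT1, 2 of the TRIB1 and 1 of the HS3ST1 peaks. The non-coding genes LOC100507065 (30 peaks), LOC101927827 (28), LOC101928381 (28) and LINC01189 (26) completed the 10 genes with most peaks. The last 3 lie on chromosome 9, and the peaks of LOC101928381 were spread over 27.6 Mb.

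Because β-catenin resists degradation in these cells, the next question was whether APC peaks lie near WNT genes. WNT target genes were linked to peaks more often than random genes: 25 of 34 had a peak within 10 kb of the TSS (73.5%), against a middle 95% range of 35.3 to 67.6% over 10000 random lists of protein-coding genes (adjusted permutation p = 0.0266, two-sided, list membership redrawn over genes, Benjamini-Hochberg over 19 lists). CCND1, the cyclin D1 gene, had a 13036-bp peak over its first intron and TSS region (chromosome 11, 69450359 to 69463393). BIRC5, the survivin gene, had a 7619-bp peak, AXIN2, the feedback scaffold of β-catenin degradation, a 6736-bp promoter peak (chromosome 17, 63555275 to 63562009), and VEGFA a 6683-bp peak. The WNT target share was the lowest of the 8 lists linked more often than random lists. Highly transcribed housekeeping genes stood at 92.9% and ribosomal protein genes at 82.7%. Random lists were not matched for transcription, so whether WNT targets are linked more often than other transcribed genes was not tested. Genes were linked by the named gene only, genes were not replicates, and the p describes this library. The call was lost for peak centres within 1 kb (adjusted permutation p = 0.144) or 50 kb (adjusted permutation p = 0.122). It was also lost against a background of genes named for any peak, which itself selects on having a peak (adjusted permutation p = 0.404). The adjusted p ranged from 0.00095 to 0.404 over 12 alternatives. The 1-kb setting drops CCND1 (centre at 1003 bp), MYC (1112 bp) and CD44 (2677 bp), whose peaks cover the TSS. The same rule lowered the linked share of all background genes from 50.9% to 35.1%, and the 7 other lists linked more often kept their calls under it. Peaks covering a TSS were not counted for background genes. Whether the starts of WNT targets are covered more often than others was therefore not tested.

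Of 25 WNT, AP-1 and colon genes named whatever their values, 21 had a peak centre within 10 kb and 17 within 1 kb of the TSS. The 17 leave out CCND1, MYC and CD44, whose peaks cover the TSS but have their centre farther than 1 kb from it. Peaks covered the starts of TCF7 (2503 bp long), LGR5 (2655 bp), an intestinal stem cell receptor, SP5 (2165 bp), DKK1 (2435 bp), a secreted WNT inhibitor, and RNF43 (1381 bp), a ubiquitin ligase that removes WNT receptors. MYC had 3 peaks within 10 kb. The closest, 5093 bp long (chromosome 8, 128746882 to 128751973), was centred in the first intron 1112 bp downstream of the TSS and covered the TSS. CD44 had a 6585-bp peak centred 2677 bp downstream of the TSS, which it also covered. ASCL2 had 2 peaks, the closest a 1088-bp peak 6033 bp upstream. CTNNB1, which encodes β-catenin, had a 1290-bp promoter peak, and GSK3B one of 2566 bp. For APC itself the closest peak was 530 bp long, centred in a SINE, and lay in the second intron 19728 bp downstream of the TSS. The one AXIN1 peak lay 25109 bp downstream, in an intron. No peak was named for LEF1.

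WNT pathway components did not pass the test: 30 of 46 were linked (65.2%, random range 37.0 to 65.2%, adjusted permutation p = 0.101). Besides BCL9L, their longest linked peaks were at TCF7L2, a DNA-binding partner of β-catenin (6402 bp, with 18 peaks in all), WNT3 (5818 bp) and LRP5 (5799 bp). This list passed without SINE-centred peaks (adjusted permutation p = 0.0355) and for links within 50 kb (adjusted permutation p = 0.0165) or at any distance (adjusted permutation p = 0.00532), with a range of 0.00532 to 0.943 over 12 alternatives.

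AP-1 factors are the JUN and FOS family of stress and growth-signal regulators, and 19 of 26 AP-1 and ATF genes were linked (73.1%, random range 30.8 to 69.2%, adjusted permutation p = 0.0544, and 0.0441 to 0.808 over 12 alternatives). JUNB (6557 bp), FOSL1 (6222 bp), JUN (3391 bp) and FOS (3455 bp) each had a promoter peak, as did ATF5 (6211 bp). ATF4 had an 11879-bp peak and ATF3 2 linked peaks, the one nearest its TSS 3858 bp long. No peak was named for JUND, but a 14116-bp peak (chromosome 19, 18381465 to 18395579) was named for KIAA1683 (now IQCN), the gene next to JUND. By the listed distances this peak takes in the TSS of IQCN and that of MIR3188, the gene on the other side of JUND. JUND may therefore lie under it. MAPK pathway and AP-1 target genes were linked in 31 of 40 cases (77.5%, adjusted permutation p = 0.00434), with peaks of 16905 bp at LIF, 11186 bp at IER2, 8382 bp at the DUSP5 promoter and 7401 bp at the EGR1 promoter. The DUSP6 promoter peak was 4912 bp long.

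Lists of growth and general cell functions were linked more often than random lists as well. Of these, the housekeeping and ribosomal lists had been fixed beforehand to stand for open or highly transcribed chromatin, as had the colon and histone lists. The share was 92.9% for highly transcribed housekeeping genes (26 of 28, adjusted permutation p = 0.00095), with the longest peaks at GAPDH (10547 bp), TPI1 (10143 bp), EEF2 (8944 bp) and FTL (7659 bp). It was 88.9% for the hippo pathway and YAP targets (24 of 27, adjusted permutation p = 0.00095), which included AXL (9005 bp), AJUBA (5580 bp), NF2 (4696 bp) and YAP1 (3639 bp). Ribosomal protein genes stood at 82.7% (43 of 52, adjusted permutation p = 0.00095), led by RPL8 (16812 bp), RPS16 (12486 bp), RPS15 (11107 bp) and RPL38 (7025 bp). DNA repair genes stood at 80.6% (29 of 36, adjusted permutation p = 0.00304), led by ERCC1 (7656 bp), FANCA (6521 bp), MSH6 (4318 bp) and FEN1 (3166 bp). Cell cycle genes stood at 78.9% (30 of 38, adjusted permutation p = 0.00434), led by CDT1 (19714 bp), CDC25B (6702 bp), MCM7 (6430 bp) and CDKN1A (5720 bp), the p21 inhibitor. Apoptosis genes stood at 78.1% (25 of 32, adjusted permutation p = 0.00617), led by TNFRSF1A (5182 bp), BCL2L1 (4678 bp) and TNFRSF10B (4643 bp). Among 20037 protein-coding genes, 50.9% were linked. Random lists were not matched for transcription. Whether the MAPK, hippo, repair, cell cycle and apoptosis lists are linked more often than other transcribed genes was therefore not tested. The series has no immunoprecipitation with a control antibody, so APC binding cannot be told apart from general recovery of open chromatin. Against a background of genes named for any peak, which keeps every linked gene and drops genes without any named peak, such as 8 of the 52 ribosomal members, the ribosomal list alone passed (adjusted permutation p = 0.0038, with a range of 2.07e-05 to 0.0255 over 12 alternatives). The apoptosis call was lost in 3 and the DNA repair call in 2 of 12 alternatives.

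Microtubule and cytoskeleton partners of APC (22 of 31, 71.0%, adjusted permutation p = 0.0544) and histone genes (14 of 23, 60.9%, adjusted permutation p = 0.508) did not pass, although the former passed in 5 of 12 alternatives (adjusted permutation p from 0.0165 to 0.808). The longest linked peaks of the former were at ACTG1 (14248 bp), ACTB (7834 bp), TUBB4B (6262 bp) and TUBB (5147 bp), and of the latter at H2AC11 (3802 bp), H2AC4 (3184 bp), H3C1 (3063 bp) and H2BC12 (2995 bp). Colon epithelium markers were linked at 46.7% (14 of 30, adjusted permutation p = 0.775). Long peaks were named for CLDN4, KRT8 (10616 bp), KRT19 (8005 bp) and CLDN7 (6678 bp), and shorter ones lay at the starts of EPCAM (4543 bp) and CDX2 (2709 bp). No peak was named for KRT18, whose neighbour KRT8 had 5. The 10616-bp peak (chromosome 12, 53338093 to 53348707) was annotated to a non-coding transcript. It lay apart from the 6712-bp peak at a KRT8 promoter (53295564 to 53302274). As a peak names 1 gene, the 10616-bp peak may lie at KRT18, which cannot be told here.

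Of 6 lists fixed beforehand as genes of other cell types, 2 were linked less often than random lists and 4 did not pass. The HOX list was among the 6, although HOX genes are not markers of 1 cell type. Olfactory receptor genes had 4 of 36 members linked (11.1%, adjusted permutation p = 0.00095), namely OR1F1, OR1K1, OR2M2 and OR5K1, with peaks of 606 to 2252 bp. Fibroblast and muscle markers had 8 of 28 (28.6%, adjusted permutation p = 0.0471), among them CKM (3423 bp), TNNI3 (3176 bp), COL1A1 (2510 bp) and MYL2 (2212 bp), and this call was lost in 7 of 12 alternatives. Liver markers had 9 of 30 (30.0%, adjusted permutation p = 0.0544, passing in 7 of 12 alternatives), the longest peak, at CYP1A2, being 1639 bp, ahead of F2 (1405 bp), HP (1177 bp) and CYP8B1 (1120 bp). HOX genes (14 of 37, 37.8%, adjusted permutation p = 0.195), neuronal markers (12 of 30, 40.0%, adjusted permutation p = 0.376) and immune markers (13 of 30, 43.3%, adjusted permutation p = 0.526) did not pass, although the HOX and immune lists each passed in 1 of 12 alternatives. Among their longest peaks were those at HOXB8 (13521 bp), HOXB6 (7050 bp), HOXB9 (6858 bp) and HOXA10 (4989 bp), at TUBB3, SLC17A7 (4130 bp), GAD1 (3837 bp) and GRIN1 (3384 bp), and at CD4 (4001 bp), PRF1 (3768 bp) and CD68 (3213 bp).

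**Figure D3:**
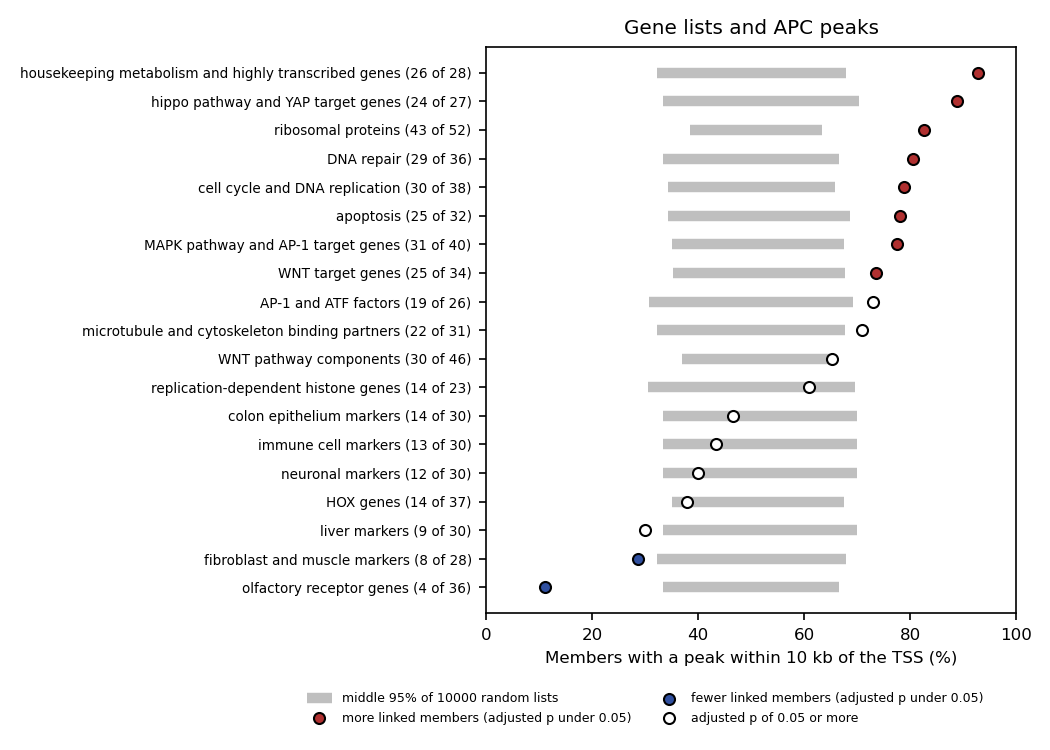
Percent of the members of each of 19 gene lists with a peak within 10 kb of the TSS (points, counts beside the names), with the middle 95% of 10000 random lists of the same size as grey bars. Filled points passed an adjusted p of 0.05; 10 lists lie above their bars, of which 8 passed, led by housekeeping genes at 92.9%, and olfactory receptor genes lie lowest at 11.1%.

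Peaks were unevenly spread over chromosomes. Chromosome 19 had 34.0 peaks per Mb between its first and last peak and chromosome 17 had 33.4, against 12.1 on chromosome 4 and 9.08 on chromosome 18. Chromosome X had 569 peaks, or 3.67 per Mb, the lowest density after chromosome Y. Per named gene, X had 1.55 peaks (exact 95% Poisson interval 1.43 to 1.69), below all autosomes, which ranged from 1.92 on chromosome 19 to 3.28 on chromosome 8. Genes without a named peak do not enter this ratio, so it does not correct for gene density. Chromosome Y had 16 peaks.

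**Figure D4:**
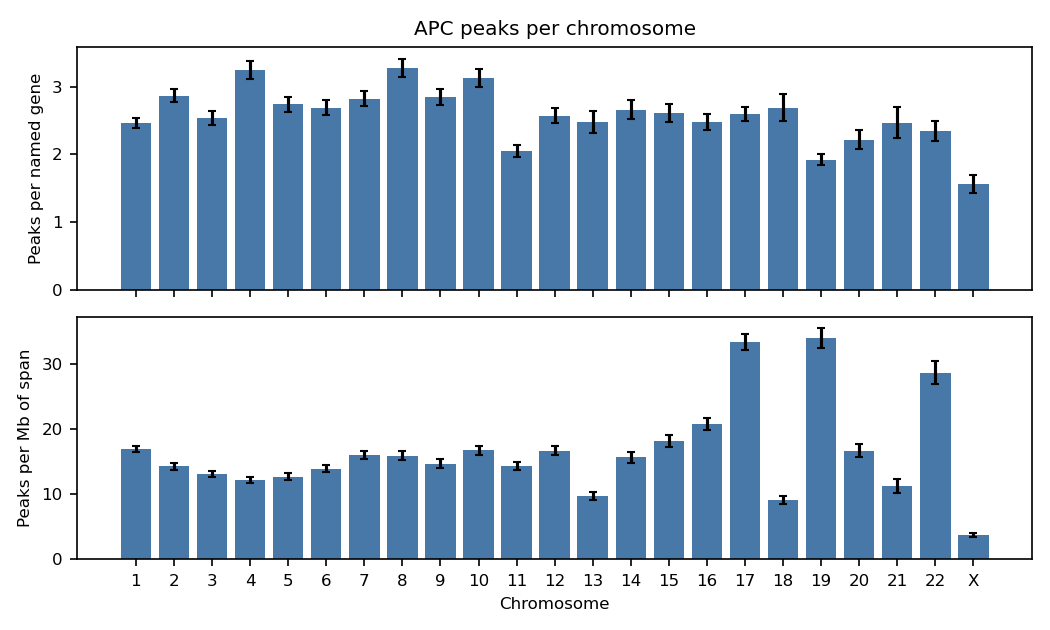
Peaks per gene named on the chromosome (top) and per Mb between the first and last peak (bottom) for chromosomes 1 to 22 and X, with exact 95% Poisson intervals as error bars. Chromosome X is lowest on both scales, at 1.55 peaks per gene and 3.67 per Mb.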

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

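The tests in this part were chosen after the result was seen. The detailed annotation, which the comparisons between gene lists did not use, places 17346 peak centres in SINE repeats, 2642 in LINE, 2204 in LTR and 610 in DNA repeats, 306 in simple repeats, 148 in low-complexity sequence, 54 in satellites and 11 in rRNA repeats. The counts are given because they come from a column outside the main comparisons, and they were not tested for enrichment.

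SINE-centred peaks made up 38.7% of the list (Wilson interval 38.3 to 39.2), and 95.7% of them lay in Alu elements, the primate-specific SINE family. They were short, with a median of 889 bp against 1543 bp for intergenic peaks outside repeats, and 20.7% lay within 10 kb of a TSS. Repeat labels were given almost only to intronic and intergenic peaks, so the low share near a TSS is partly built in. If the centres of short and long peaks fell alike by chance into an abundant repeat, the shares would be equal. Among peaks over 10 kb from a TSS, the SINE-centred share was 58.9% below and 32.6% above the median length, a difference of 26.4 percentage points. Long peaks can lie in sequence with fewer repeats, and the SINE share of the genome was not used here. Chance placement of the short peaks therefore cannot be excluded. Reads shared between near-identical repeat copies may contribute: AluY, the youngest and least diverged Alu subfamily, made up 22.8% of Alu-centred peaks below and 13.9% above the median length, a difference of 8.93 percentage points, while AluJ, the oldest, made up 13.0% and 20.8%. Binding of APC at young Alu elements would give the same difference and stays open, and no biological explanation was tested, since the design has 1 ChIP library.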

How the results depend on the processing

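The share of promoter peaks (11.2%) was 19.1% among peaks of 1350 bp or more, 22.0% among peaks of 2135 bp or more and 18.3% without SINE-centred peaks. The share within 1 kb of a TSS (18.1%) was 30.4%, 34.8% and 29.2%. Promoter peaks almost never carry a repeat label. Leaving out SINE-centred peaks therefore raises the promoter share by construction, and in part the share near a TSS. Merging peaks and leaving out satellite, simple, low-complexity and rRNA repeats kept both shares within their intervals. The difference in median length between promoter and intergenic peaks turned to -165 bp, and that between promoter and intronic peaks to -71 bp (permutation p = 0.00423), among peaks of 2135 bp or more, a setting that by construction holds only long peaks of every class. Of 19 lists, 10 were called; between 9 and 13 were called under the other alternatives, but 1 against genes named for any peak. That background (13524 genes) selects on the outcome, keeping every linked gene and dropping genes without a named peak, so lost calls there do not show the calls to be weak. For WNT targets the excess of the linked share over the background fell from 22.6 to 14.9 percentage points within 1 kb, 15.4 within 50 kb and 10.8 against genes named for any peak, each without a call. WNT components gained a call without SINE-centred peaks (17.6 points), within 50 kb (18.6) and at any distance (21.6). AP-1 and ATF factors gained one among peaks of 2135 bp or more (21.6), at any distance (21.0) and by Fisher's exact test (22.2, adjusted p = 0.0441; range over 12 alternatives 0.0441 to 0.808). The cause was not tested. Ribosomal proteins were called in all 12 alternatives. Over all 19 lists, 188 of the values under an alternative kept their side of the threshold, 20 gained and 20 lost a call, and none turned in direction with a call. Chromosome X had 1.37 peaks per named gene among peaks of 1350 bp or more and 1.40 without SINE-centred peaks, against autosomal minima of 1.51 and 1.54. The FOSL1 link was lost on merging, where a longer neighbouring peak gave the name, and CTNNB1 and ASCL2 kept no linked peak of 1350 bp or more. MYC, CCND1, CD44 and ASCL2 lost their link within 1 kb, which counts peak centres. A few further settings were not run: leaving out unplaced sequence removes no peak, other strength columns were not used here, comparing lengths within classes of width would fix the measure itself, and motifs need a genome sequence. Without read depth, no statement is made on weak or undetected sites. No paired analysis was possible because the series has 1 ChIP and 1 input library.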

Other observations

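The lists and tests of this part were chosen after the peaks were seen, except the 2 length tests on chromosome X, which were fixed before their values were known. Peaks of 5 kb or more, 1381 in all (3.08% of peaks), lay within 10 kb of the TSS of 623 of the 20037 protein-coding genes (3.11%). By the same random-list test, 7 of the 19 lists had more members with such a peak than random lists. WNT targets had 7 of 34 (adjusted permutation p = 0.0038), namely AXIN2, BIRC5, BMP4, CCND1, CD44, MYC and VEGFA. WNT components had 6 of 46 (adjusted permutation p = 0.0174), namely BCL9L, DVL1, GSK3A, LRP5, TCF7L2 and WNT3. AP-1 and ATF factors had 5 of 26 (adjusted permutation p = 0.00912), namely ATF4, ATF5, FOSL1, FOSL2 and JUNB, and MAPK and AP-1 targets had 7 of 40 (adjusted permutation p = 0.0038), among them DUSP4 and EGR1. Colon epithelium markers, which did not pass over all peaks, had 5 of 30 (adjusted permutation p = 0.0114), namely CLDN4, CLDN7, ELF3, KRT19 and KRT8. Housekeeping genes had 8 of 28 and ribosomal protein genes 9 of 52 (adjusted permutation p = 0.0019 each). Of the 8 lists linked more often over all peaks, cell cycle genes (4 of 38, adjusted permutation p = 0.136), DNA repair (2 of 36, adjusted permutation p = 0.953), hippo pathway (2 of 27, adjusted permutation p = 0.701) and apoptosis genes (1 of 32, adjusted permutation p = 1) did not pass. Differences between lists were not tested.

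Protein-coding genes grouped by the letters of their symbol gave 53 families of at least 30 genes, the LOC placeholder symbols aside. Against a background without LOC symbols (19378 genes), 7 families were linked more often and 10 less often than random lists. With these symbols kept in the background and as a family of their own (1 of 659 linked), the counts were 10 and 11 of 54. The former included VPS genes of vesicle sorting (29 of 35), POLR genes of the RNA polymerases (27 of 33), EIF translation factors (44 of 56) and DDX helicases (29 of 38). RPS genes, which take in the RPS6K kinases, were among them (36 of 45), whereas RPL genes, with their gene copies, had 34 of 52 and did not pass (adjusted permutation p = 0.130). The latter included olfactory receptors (45 of 392), DEFB defensins (5 of 39), KRTAP hair keratin-associated proteins (14 of 94), IL genes (23 of 85) and SPATA spermatogenesis genes (10 of 39). Of the HOX clusters, HOXA had 6 of 11 members linked, HOXB 4 of 10, HOXC 2 of 7 and HOXD 2 of 9. The 500-kb window with most peaks lay on chromosome 4 (30715996 to 31179716) and held 62 peaks, all named for PCDH7, of which 37 were SINE-centred. The window on chromosome 12 with KRR1 and PHLDA1 held 57, one on chromosome 17 with VMP1 and MIR21 held 51, and one on chromosome 11 with NEAT1 and MALAT1 held 48.

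Chromosome X had few peaks, but it held 2.85% of promoter peaks against 1.27% of all peaks. The promoter share of peaks on X was 25.1% (Wilson interval 21.7 to 28.9), above the highest autosome, chromosome 11, at 14.9%. This share does not measure gene density, as it also rises where other peaks are few. Promoter peaks per Mb were 0.922 on X and 1.03, 1.05 and 1.07 on chromosomes 4, 13 and 18. All peaks per Mb were 3.67 on X and 12.1, 9.71 and 9.08 on those chromosomes. The number of genes per chromosome was not used, so the part of gene density is not settled. A lower signal on X that shortens its peaks is a candidate explanation: the median promoter peak was 1307 bp on X (143 peaks) and 2140 bp on the autosomes (4879 peaks), a difference of -833 bp (permutation p = 1e-05, the smallest possible). A detection limit that removes weaker peaks first was expected to thin the shorter intronic and intergenic peaks of X. Yet X held 1.32% of those below and 0.689% of those above the median length, a difference of 0.636 percentage points. By the rule fixed beforehand this outcome counts against such a limit. A reservation outside that rule applies: peaks on X were also shorter at promoters, so length cannot stand for strength there. With this reservation the limit cannot be told apart from shortening. The comparison of chromosomes had been planned to look for copy number or mapping effects of the cell line. Copy number was not measured here, so a lower copy number of X cannot be told apart from a difference in APC binding on X.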
